A study of Mus musculus with 64 samples.

How the data were processed

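RNA was sequenced from ventral tegmental area punches of 64 adult male mice, 1 library per mouse. The labels give the strain as 129S1/Svlm, the genotype as Wildtype or Clock delta 19 (a dominant-negative allele of the core clock gene Clock), and the treatment as valproate (VPA, a mood stabiliser that inhibits histone deacetylases), ACY957 (an inhibitor selective for class I histone deacetylases) or the vehicle of either drug. Treatment lasted 14 days and brains were taken at zeitgeber time 6, about 24 h after the last dose, with bilateral punches of 1 mm. Libraries were stranded and poly(A) selected, and were read on a NextSeq 500 at 75 bases, with 30 to 40 M reads stated per library.

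The deposited file holds raw read counts per gene symbol for 24421 symbols, and the authors applied no normalization to it. The values were checked to be whole numbers with column totals between 20.1 M and 37.5 M. The design text names FastQC 0.11.3, TopHat2 2.0.9 and HTSeq 0.6.1 in union mode on mm10, a human genome as a further alignment target, and a voom transformation that the file does not carry. The submitters' processing notes name FastQC, Trimmomatic, HISAT2 and HTSeq, so the aligner differs between these sources. Of the symbols, 23376 matched GENCODE M21, which gave positions on mm10, and 3945 had no count in any library. No mitochondrially encoded gene was in the file, so the list of these genes planned before the data were examined gave no result.

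Groups followed the labels, and no library was moved. The design text gives 8 mice for each of 2 genotypes and 4 treatments, but the vehicle labels gave 3 and 5 mice labelled wildtype and 13 and 11 labelled mutant. The 16 vehicle libraries labelled mutant from mouse 48 on were therefore left out in a repeat of each test that was fixed before the data were examined. That repeat kept replicates 1 to 4 of each vehicle group labelled mutant, so a result lost there may also reflect fewer libraries. Genotype labels were checked with a clock output score, the mean log2 CPM (counts scaled to the library total) of 8 genes (Dbp, Tef, Per2, Per3, Nr1d1, Nr1d2, Ciart, Bhlhe41).

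Counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr, quasi-likelihood F tests) in 1 model with a mean for each of the 8 groups over all 64 libraries, which left 15634 genes. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Values are given as log2 fold changes with approximate standard errors (SE), and as mean CPM with the SD between libraries. The SE is the size of the log2 fold change over the square root of its F statistic. A count such as 8 of 8 libraries gives those past the median of the other group, unless the extreme is named. There were 14 planned comparisons: the genotype labels within each of 4 treatments, each drug against its vehicle within each genotype label, both interactions, the difference between the drug effects within each label, and the vehicles against each other. Another 3 comparisons, of the treatments over both genotype labels (14983 genes tested), were added after the data were examined.

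Gene lists, 35 fixed as symbols and 1 of ribosomal proteins fixed as a naming rule, were tested in each comparison with camera at a preset correlation of 0.01, adjusted over the 36 lists. They were tested again with an estimated correlation and with fry (limma 3.58.1). Members were also counted with p-values adjusted over the list alone. Named genes followed a rule fixed before the data were examined: Clock in every comparison, the 10 genes with the smallest p in each direction among those that passed, up to 12 passing list members, and the 5 with the smallest p where fewer than 5 passed, with predicted genes skipped and repeats left out for length. A few genes that the rule or the lists name are not reported here. Fold changes were correlated across genes between 7 pairs of comparisons without shared libraries, against 100 permutations of library labels. Genes were not treated as independent replicates in that test.

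Each result was recomputed, by choices fixed before the data were examined, with DESeq2 1.42.0, limma voom, no low-count filter, a fit of the compared groups alone, up to 5 surrogate variables (sva 3.50.0), the model without the 16 libraries, pooled vehicles, and leaving out each wildtype-labelled vehicle library. Leaving out every other library in turn, leaving out 4 libraries with Th under 8 log2 CPM, Th as a covariate, leaving out 13 libraries discordant in clock output (not for genotype comparisons, where it would select on the outcome), a genotype term, and a correction for transcript length and GC content were added after the data were examined. For each comparison, 40 splits of its libraries into groups of the same sizes, the real 1 included, were fitted.

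The procedure was tested on simulated counts with independent genes. In groups of the sizes compared it recovered 73.1% of 1.5-fold and 94% of 2-fold changes for the genotype labels in VPA-treated mice, and 52.2% and 81.8% for VPA in mice labelled wildtype. These shares contain no variation in dissection.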

Results

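Gene expression in the ventral tegmental area, the midbrain region that holds mesolimbic dopamine neurons, was measured by RNA sequencing in 64 mice. The labels put 8 libraries in each of the 4 drug-treated groups, VPA or ACY957 in mice labelled wildtype or Clock mutant. The VPA vehicle groups held 3 libraries labelled wildtype and 13 labelled mutant, and the ACY957 vehicle groups 5 and 11. Total counts per library ranged from 20.1 M to 37.5 M reads, with a median of 25.8 M, and correlations between libraries ranged from 0.956 to 0.9928. Th (chromosome 7, 142892752 to 142931128, minus strand), which encodes the rate-limiting enzyme of dopamine synthesis, was at 977 CPM (SD 486, n = 8) in VPA-treated libraries labelled wildtype, and 4 of the 64 libraries lay under 8 log2 CPM.

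The genotype labels were first set against the output of the clock, since the number of vehicle mice per label differed from the design. The clock output score separated the libraries into a lower set, at or under 4.33 log2 CPM, and an upper set, at or above 4.91 log2 CPM. Of the 24 libraries labelled wildtype, 23 lay in the upper set. Of the 40 labelled mutant, 28 lay in the lower set and 12 in the upper. In VPA-treated mice the mean score was 5.17 (SD 0.12, n = 8) under the wildtype label and 4.27 (SD 0.31, n = 8) under the mutant label. In VPA vehicle mice labelled mutant it was 4.57 (SD 0.61, n = 13), with 6 libraries in the upper set, and in ACY957 vehicle mice labelled mutant it was 4.46 (SD 0.56, n = 11), with 3 in the upper set. In drug-treated mice 1 VPA and 2 ACY957 libraries labelled mutant lay in the upper set, and 1 ACY957 library labelled wildtype in the lower. Every genotype comparison therefore mixes both levels of clock output under the mutant label, and the values that follow compare labels.

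**Figure D1:**
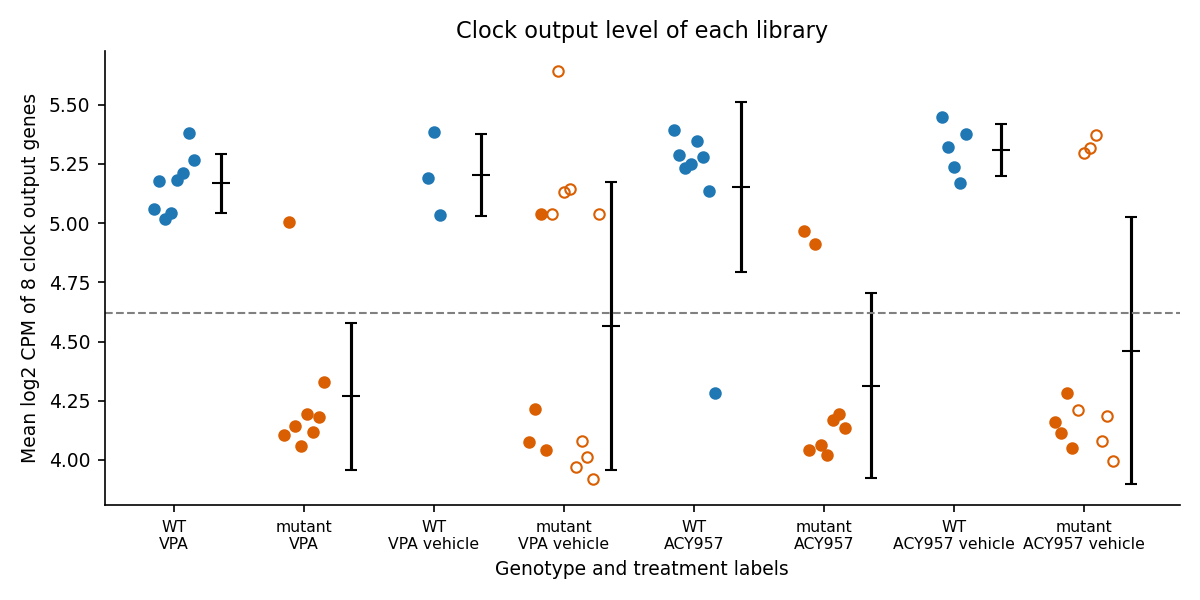
Mean log2 CPM of 8 clock output genes (vertical axis) in each of the 64 libraries by genotype and treatment label (horizontal axis). Points are libraries, open points the 16 vehicle libraries labelled mutant from mouse 48 on, bars the group mean and SD, and the dashed line the midpoint of 4.62 between the sets, with 13 libraries on the side of the other label.

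The genotype comparison in VPA-treated mice asked how expression differed between the genotype labels under the drug, with 8 libraries on each side. Mice labelled wildtype are numbered 1 to 24 and mice labelled mutant 25 to 64. In every genotype comparison the label therefore cannot be told apart from anything that runs with mouse number, and the labels give no batch. Clock itself (chromosome 5, 76209868 to 76304792 on mm10, minus strand) was at 66.1 CPM (SD 5.94, n = 8) under the wildtype label and 69 CPM (SD 7.24, n = 8) under the mutant label, a log2 fold change of 0.06 (SE 0.10, adjusted p = 0.825, edgeR). Of 17 core clock genes, 5 fell and 1 rose under the mutant label over all genes tested, and 9 fell and 1 rose when adjusted over the list alone. Per2 (chromosome 1, 91415982 to 91459324, minus strand), a repressor in the clock loop, fell by 1.42 (SE 0.35, adjusted p = 0.0278, edgeR), from 7.95 CPM (SD 1.41, n = 8) to 2.96 CPM (SD 2.17, n = 8), and lay under the wildtype-label median in 7 of 8 libraries. Cry2, another repressor, fell by 0.65 (SE 0.14), Bhlhe41 fell by 0.52 (SE 0.13), and Arntl, the partner of Clock, rose by 0.73 (SE 0.14, adjusted p = 0.00345, edgeR) from 14.7 to 24.3 CPM, each in 8 of 8 libraries. Of 14 clock output genes, 4 fell over all genes tested, and 5 fell and 3 rose when adjusted over the list alone. Dbp (chromosome 7, 45705088 to 45710203, plus strand) fell by 1.04 (SE 0.26), Tef fell by 0.59 (SE 0.15) and Coq10b fell by 0.47 (SE 0.10), each in 8 of 8 libraries. The camera calls for core clock (adjusted p = 4.42e-06) and clock output (adjusted p = 0.00357) were lost with an estimated correlation (adjusted p = 0.403 for both), while fry gave adjusted p = 0.0435 for core clock and 0.0506 for clock output.

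Outside the clock lists, Eif5a2 (chromosome 3, 28781276 to 28798846, plus strand), a translation factor, fell by 1.55 (SE 0.28, adjusted p = 0.00158, edgeR) from 282 CPM (SD 42.5, n = 8) to 96.3 CPM (SD 21.3, n = 8). Mthfd1l, a mitochondrial enzyme of folate metabolism, fell by 1.51 (SE 0.31), Fmo2, a flavin monooxygenase, fell by 2.33 (SE 0.44) and Cndp2, a dipeptidase, fell by 0.75 (SE 0.13). In each of these genes all 8 libraries labelled mutant lay under the lowest library labelled wildtype. Gapdh fell by 1.04 (SE 0.20) from a level of 9.80 CPM (SD 4.17, n = 8) to 4.78 CPM (SD 1.12, n = 8), both under the 66.1 and 69.0 CPM of Clock. The interferon-induced genes Ifit3 and Ifit3b fell by 1.22 (SE 0.23) and 1.04 (SE 0.23), and Nln, Pdk3 and Cog3 fell by 0.34, 0.27 and 0.21. The glial and endothelial genes Rlbp1 and Cldn5 rose by 0.58 (SE 0.11) and 0.55 (SE 0.14), above the wildtype-label median in 8 of 8 libraries each. They lay above the highest library labelled wildtype in 5 and 0 of 8. Emp2, Dnaic1, Adgrg1, Paqr6, Thrsp and Csad rose by 0.58, 0.76, 0.39, 0.44, 0.44 and 0.33. Of 10 astrocyte markers, 0 passed over all genes and 4 rose when adjusted over the list alone, and the camera call upward (adjusted p = 0.0322) was lost with an estimated correlation (adjusted p = 0.403).

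The largest rises among the genes that passed in VPA-treated mice were in Hcrt and Pmch, which encode hypothalamic neuropeptides. Pmch lies on chromosome 10 at 88091072 to 88092375 (plus strand) and Hcrt on chromosome 11 at 100761069 to 100762931 (minus strand) of mm10. Pmch, the precursor of melanin-concentrating hormone, was higher by 4.10 (SE 0.59, adjusted p = 4.97e-05, edgeR), at 131 CPM (SD 204, n = 8) against 7.61 CPM (SD 5.75, n = 8), and 4 of 8 libraries lay above the highest library labelled wildtype. The difference in Pmch was 2.19 without the libraries low in Th and 1.46 with Th as a covariate, and it did not pass in voom (2.29, adjusted p = 0.054) or in the fit of the compared groups alone (adjusted p = 0.0736). Its adjusted p ranged from 3.09e-10 to 0.0736 over the alternatives. Hcrt, the orexin precursor, was higher by 4.14 (SE 0.62), above the highest library labelled wildtype in 3 of 8 libraries. All 22 dopamine neuron markers were lower under the mutant label, with a median of -0.55, though 0 passed singly (0 when adjusted over the list alone). Their camera adjusted p of 4.61e-11 became adjusted p = 0.574 with an estimated correlation. Mutant-labelled replicates 2 and 8 had Th at 44 and 26 CPM, and wildtype-labelled replicate 3 at 98 CPM. The list was not tested without these libraries, so a difference in dissection was not separated from the label. Ribosomal protein genes were higher in 77 of 80, with a median of 0.14 and camera adjusted p = 4.61e-11 (adjusted p = 0.665 with an estimated correlation). Microglia, immediate early and glucocorticoid responsive lists moved down and endothelial and mural markers up by camera, and each of these calls was lost with an estimated correlation (adjusted p = 0.665 for each). In all, 157 of 15634 genes passed, 111 higher and 46 lower, with 2451 at an unadjusted p under 0.05, 262 by DESeq2 and 127 by voom. A fit of the 16 compared libraries alone gave 73 genes, of which 52 were among the 157, and the model without the 4 libraries low in Th gave 84. Single libraries moved the count. It was 59, 94, 56, 51 and 80 without VPA wildtype-labelled replicates 1, 2, 4, 5 and 6, and 504 without replicate 3, which had the lowest Th of the group. It was 96, 295, 284, 75 and 56 without VPA mutant-labelled replicates 2, 3, 6, 7 and 8.

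In ACY957-treated mice the same question gave 0 genes past the threshold in edgeR, with 757 at an unadjusted p under 0.05, 5 by DESeq2 and 0 by voom, between 8 and 8 libraries. The clock output of mutant-labelled replicates 1 and 3 and of wildtype-labelled replicate 8 lay on the side of the other label. Clock was at 67.8 CPM (SD 7.87, n = 8) and 74.9 CPM (SD 6.18, n = 8), a log2 fold change of 0.14 (SE 0.10). Among core clock genes 10 fell and 2 rose when adjusted over the list alone, and among clock output genes 5 fell and 1 rose, against 0 over all genes tested. Per2 was at 6.75 CPM (SD 1.87, n = 8) under the wildtype label and 3.18 CPM (SD 1.58, n = 8) under the mutant label, and Dbp at 61.8 CPM (SD 13.3, n = 8) and 32.4 CPM (SD 11.4, n = 8). The camera adjusted p was 1.96e-08 for core clock (adjusted p = 0.0867 with an estimated correlation) and 9.24e-05 for clock output (adjusted p = 0.0994 with an estimated correlation). The smallest p belonged to Ier3, with a log2 fold change of -0.37 (SE 0.08, adjusted p = 0.0851, edgeR), Gpr155 with -0.37, Gapdh with -0.91, Patl2 with -0.90 and Epor with -0.995, none of which passed. Dopamine neuron markers were higher in 22 of 22, with a median of 0.27 (camera adjusted p = 0.000451, and adjusted p = 0.879 with an estimated correlation). This was the opposite of the direction in VPA-treated mice, whose groups held libraries low in Th, so a difference in dissection was not separated from this contrast. Oligodendrocyte markers were lower in 12 of 12, with a median of -0.17 (camera adjusted p = 0.00011; adjusted p = 0.74 with an estimated correlation). The fit of the compared groups alone gave 8 genes, and the model without the 16 vehicle libraries gave 20. Without wildtype-labelled replicate 8 the count was 2, and without mutant-labelled replicate 3 it was 1. Fold changes across genes in VPA-treated and ACY957-treated mice had a Pearson r of -0.104 (p = 0.723 against 100 permutations, adjusted p = 0.861 over the 7 correlations).

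In vehicle mice the genotype labels were compared without a drug. Clock was at 70.5 CPM (SD 13.7, n = 3) and 71.1 CPM (SD 9.23, n = 13) in VPA vehicle mice, and at 68.6 CPM (SD 3.89, n = 5) and 73.7 CPM (SD 14.5, n = 11) in ACY957 vehicle mice. With VPA vehicle, the list of dopamine receptors and signalling was lower under the mutant label: 10 of 12 were lower, with a median of -0.40, and 6 fell when adjusted over the list alone, among them Adora2a, Drd1 and Ppp1r1b, while 0 passed over all genes. This list's call held with an estimated correlation (adjusted p = 0.0173) and in fry (adjusted p = 0.0139). Drd1, the D1-type receptor, was at 13.1 CPM (SD 4.39, n = 3) and 7.01 CPM (SD 3.12, n = 13). Microglia markers were lower in 12 of 12, with 5 that fell when adjusted over the list alone, among them Csf1r and Cx3cr1, and 0 over all genes (camera adjusted p = 1.59e-10; adjusted p = 0.118 with an estimated correlation). Ackr2, an atypical chemokine receptor, fell by 2.50 (SE 0.46, adjusted p = 0.0197, edgeR), from 2.14 CPM (SD 2.76, n = 3) to 0.378 CPM (SD 0.13, n = 13), and no longer passed without wildtype-labelled VPA vehicle replicate 3 (adjusted p = 0.735), in voom (adjusted p = 0.972) or in the fit of the compared groups alone (adjusted p = 0.301). It was the 1 gene that passed, with 805 at an unadjusted p under 0.05, 2 by DESeq2 and 1, Lect1, by voom. Lect1 (-1.27), Stoml1 (0.29), Ctsc (-0.42) and Ido1 (-1.08) followed without passing. The fit of the compared groups alone gave 0 genes, and the count was 0 without wildtype-labelled VPA vehicle replicate 3 and 2 without mutant-labelled VPA vehicle replicate 1 or 9.

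With ACY957 vehicle, core clock genes fell in 8 and rose in 1 when adjusted over the list alone, and clock output genes fell in 6 and rose in 1, with 0 over all genes in both lists. Their camera calls (adjusted p = 9.07e-07 and 6.14e-05) were lost with an estimated correlation (adjusted p = 0.109 for both). Per2 was at 7.1 CPM (SD 1.45, n = 5) and 3.56 CPM (SD 2.68, n = 11). Gapdh fell by 1.17 (SE 0.21, adjusted p = 0.00409, edgeR), from 10.1 to 4.47 CPM, and did not pass without wildtype-labelled ACY957 vehicle replicate 2 (-1.07, adjusted p = 0.194). Over the alternatives its adjusted p ranged from 7.93e-05 to 0.194. Gapdh did not go with clock output here: mutant-labelled replicates 6, 7 and 8, in the upper set, were at 5.05, 4.43 and 3.84 CPM, under the lowest wildtype-labelled library (7.26 CPM). It was also low in wildtype-labelled ACY957 replicates 7 and 8 (4.02 and 4.88 CPM). Tuba1c, a tubulin, passed with -0.94 (SE 0.16, adjusted p = 0.00267, edgeR), at 12.3 CPM (SD 9.08, n = 5) and 6.44 CPM (SD 0.719, n = 11), but the difference rested on that same library: without it Tuba1c had -0.36 (adjusted p = 1). Tuba1c also did not pass in voom (adjusted p = 0.129) or in the fit of the compared groups alone (adjusted p = 0.962), and its adjusted p ranged from 0.000137 to 1 over the alternatives. These 2 genes passed, with 565 at an unadjusted p under 0.05, 2 by DESeq2 and 1 by voom. Krt28 (1.70), Vip (-1.22) and Slc6a4 (-4.65) followed without passing. Under the wildtype label the SD exceeded the mean for Vip and for Slc6a4 (1.58 CPM, SD 3.42, n = 5). Without wildtype-labelled ACY957 vehicle replicate 2 the count was 0, and without the 16 vehicle libraries it was 22.

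**Figure D2:**
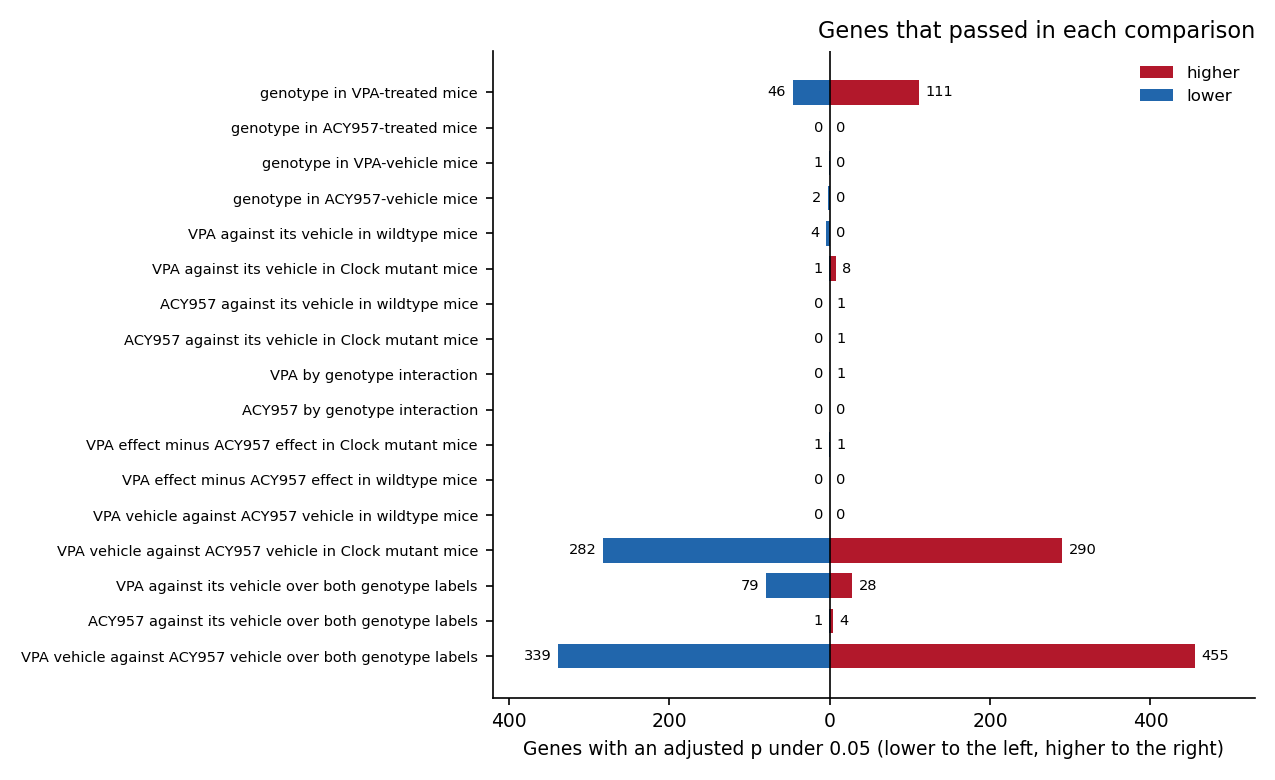
Number of genes with an adjusted p under 0.05 in edgeR (horizontal axis, lower to the left and higher to the right of 0) in each of the 14 planned comparisons and the 3 added ones (vertical axis). The comparison of vehicles in mice labelled mutant, with 290 higher and 282 lower, exceeds every comparison of a drug with its vehicle.

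VPA was compared with its vehicle to find the genes that respond to the drug. In mice labelled wildtype (8 against 3 libraries) Clock had a log2 fold change of -0.09 (SE 0.13). Lect1, an extracellular matrix gene also known as chondromodulin, fell by 1.41 (SE 0.28, adjusted p = 0.0224, edgeR), from 2.6 CPM (SD 0.495, n = 3) to 0.978 CPM (SD 0.369, n = 8). Igfbp5, an insulin-like growth factor binding protein, fell by 0.78 (SE 0.15) from 182 to 106 CPM, Padi2, a peptidylarginine deiminase of oligodendrocytes, fell by 0.84 (SE 0.18) and Rlbp1 fell by 0.70 (SE 0.14), each in 8 of 8 libraries. These 4 genes passed, with 668 at an unadjusted p under 0.05, 6 by DESeq2 and 3 by voom. Ackr2 followed with -2.35 (adjusted p = 0.0615, edgeR). In the fit of the compared groups alone Lect1 and Rlbp1 did not pass (adjusted p = 0.32 for both), Padi2 did not pass in voom (adjusted p = 0.0771), and Lect1 did not pass with both vehicles pooled (adjusted p = 0.0806). Over the alternatives the adjusted p ranged from 0.00385 to 0.535 for Lect1, from 0.00223 to 0.579 for Rlbp1 and from 0.000929 to 0.606 for Padi2. Cholesterol synthesis genes were lower in 17 of 17, with a median of -0.18, and 2 fell when adjusted over the list alone, Cyp51 and Msmo1, against 0 over all genes (camera adjusted p = 4.15e-08; adjusted p = 0.256 with an estimated correlation). Glucocorticoid responsive genes were higher in 13 of 13, with a median of 0.49 and 0 past the threshold over all genes or over the list alone (camera adjusted p = 2.55e-07; adjusted p = 0.243 with an estimated correlation). The cold responsive genes Cirbp and Rbm3 rose when adjusted over the list alone, by 0.46 and 0.63, with 0 over all genes (camera adjusted p = 0.0151; adjusted p = 0.243 with an estimated correlation). The count fell to 0 without VPA replicate 5 or vehicle replicate 2 of this label, to 1 without vehicle replicate 3, and to 2 without VPA replicate 6 or vehicle replicate 1.

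In mice labelled mutant (8 against 13 libraries) Clock had a log2 fold change of -0.04 (SE 0.09). Pmch rose by 4.23 (SE 0.49, adjusted p = 7.77e-08, edgeR) over 7.02 CPM (SD 3.21, n = 13) in vehicle, Hcrt by 4.36 (SE 0.53) and Tac2, the neurokinin B precursor, by 2.72 (SE 0.50). They lay above the vehicle median in 6, 6 and 4 of 8 libraries. Pmch had 1.99 without the libraries low in Th and 1.59 with Th as a covariate, and did not pass in voom (2.30, adjusted p = 0.206), with surrogate variables (1.35, adjusted p = 0.192), in the fit of the compared groups alone (adjusted p = 0.0586) or without the 16 vehicle libraries (adjusted p = 0.442). Its adjusted p ranged from 3.1e-14 to 0.442 over the alternatives. Car9, Fam47e, Ramp3, Calcr and Brs3 rose by 3.60, 2.75, 1.30, 1.68 and 2.26. They lay above the vehicle median in 7, 7, 6, 4 and 5 of 8 libraries and above the highest vehicle library in 2, 3, 3, 2 and 3. Under VPA their SD exceeded the mean, as for Car9 (0.976 CPM, SD 1.60, n = 8) and Calcr (8.81 CPM, SD 10.2, n = 8). Mcm2, a DNA replication factor, fell by 0.52 (SE 0.10, adjusted p = 0.0108, edgeR), in 8 of 8 libraries. These 9 genes passed, 8 higher and 1 lower, with 1976 at an unadjusted p under 0.05, 28 by DESeq2 and 0 by voom. Across all 64 libraries Th was lower where the mean of hypothalamic markers was higher (Pearson r = -0.637, permutation p = 1e-05, the smallest that the permutations can give, Spearman rho = -0.496, permutation p = 6e-05, r = -0.585 without the 2 farthest libraries). Th was at 650 CPM (SD 538, n = 8) under VPA and 789 CPM (SD 363, n = 13) under vehicle, and 21 of 22 dopamine neuron markers were lower, with 0 past the threshold over all genes or over the list alone (camera adjusted p = 1.4e-08; adjusted p = 0.629 with an estimated correlation). Oligodendrocyte markers were lower in 12 of 12, with a median of -0.23, and 4 fell when adjusted over the list alone, among them Mag and Mbp, against 0 over all genes (camera adjusted p = 3.49e-05; adjusted p = 0.604 with an estimated correlation). The count was 0 without the 16 vehicle libraries and in the fit of the compared groups alone, 2 without the libraries low in Th, and 130 with both vehicles pooled. It was 123, 3, 135, 196, 48, 73 and 4 without VPA mutant-labelled replicates 1, 2, 3, 4, 5, 6 and 8, and 46, 269 and 22 without mutant-labelled VPA vehicle replicates 1, 3 and 10.

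**Figure D3:**
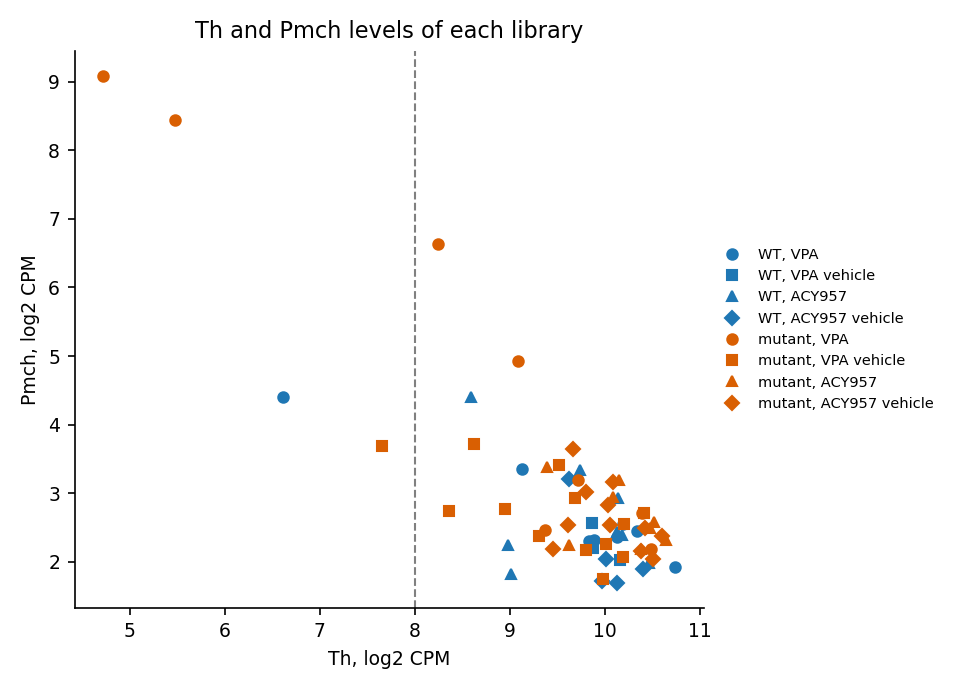
Th (horizontal axis, log2 CPM) and Pmch (vertical axis, log2 CPM) in each of the 64 libraries, with color for the genotype label and shape for the treatment. The dashed line marks 8 log2 CPM of Th, with 4 libraries under it, 2 of them VPA-treated and labelled mutant.

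The difference of the VPA effect between labels was tested directly. Lect1 passed with 1.82 (SE 0.34, adjusted p = 0.029, edgeR), with 444 genes at an unadjusted p under 0.05 and 1 gene each by DESeq2 and voom. Clock had 0.05 (SE 0.16), and Rlbp1 (0.75), Snhg17 (-1.12), Pmch (3.56, adjusted p = 1) and Slc1a5 (-0.84) followed without passing. Lect1 no longer passed without the 16 vehicle libraries (1.53, adjusted p = 1), nor without any of the wildtype-labelled vehicle libraries (replicates 1, 2 and 3, with adjusted p = 0.0955, 0.0705 and 0.892). The count was also 0 without VPA wildtype-labelled replicate 2 or 5, VPA mutant-labelled replicate 2, 4 or 5, or mutant-labelled VPA vehicle replicate 5, 10 or 13, and 2 without VPA wildtype-labelled replicate 3. Fold changes of VPA under the wildtype and mutant labels had a Pearson r of 0.322 across genes (p = 0.0495 against 100 permutations, adjusted p = 0.243 over the 7 correlations), and 0.169 without the 16 vehicle libraries.

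Over both labels, a comparison added after the data were examined, 16 VPA libraries were set against 16 vehicle libraries. Clock had -0.07 (SE 0.07). Ugt8a, a myelin lipid enzyme, fell by 0.45 (SE 0.11), Enpp6 by 0.44 (SE 0.11), Bcas1 by 0.41 (SE 0.10) and Pmp22, a myelin protein, by 0.43 (SE 0.09), in 15 or 16 of 16 libraries. Of 12 oligodendrocyte markers 1 fell over all genes and 5 when adjusted over the list alone (camera adjusted p = 7.16e-06; adjusted p = 0.37 with an estimated correlation). Of 7 oligodendrocyte precursor markers 2 fell over all genes and 2 when adjusted over the list alone (camera adjusted p = 0.00385; adjusted p = 0.37 with an estimated correlation). Aqp4, the astrocyte water channel, fell by 0.45 (SE 0.11), and the lipid enzymes Scd1 and Acat3 fell by 0.26 (SE 0.05) and 0.46 (SE 0.10). Pbk, a mitotic kinase, fell by 1.86 (SE 0.37), Fbxo32, a muscle ubiquitin ligase subunit, by 0.47 (SE 0.09), and Bfsp2, Igfbp5, Pmel, Aplnr, Dock5 and Enpp2 by 0.69, 0.40, 0.50, 1.39, 0.46 and 0.30. Cryz, Heph, Cd24a, Rnase4, Sparc, Prkcd and Eif4b rose by 0.30, 0.44, 0.63, 0.32, 0.33, 0.48 and 0.15, and Pmch, Hcrt and Tac2 by 3.40, 3.59 and 1.90. These last 3 lay above the vehicle median in 8, 13 and 9 of 16 libraries and above the highest vehicle library in 5, 4 and 5, with Pmch at 69.2 CPM (SD 153, n = 16). Cholesterol synthesis genes fell in 7 of 17 (Cyp51, Dhcr7, Hmgcs1, Idi1, Msmo1, Mvd and Nsdhl) and glucocorticoid responsive genes rose in 7 (Fkbp5, Map3k6, Mt1, Mt2, Pdk4, Sgk1 and Sult1a1) when adjusted over the list alone, with 0 over all genes in both lists. Their camera adjusted p of 5.1e-08 and 1.23e-09 became adjusted p = 0.37 with an estimated correlation. In all, 107 of 14983 genes passed, 28 higher and 79 lower, with 2003 at an unadjusted p under 0.05, 179 by DESeq2 and 113 by voom. The count was 0 in the fit of the compared libraries alone, 1 without the 16 vehicle libraries and 11 with the genotype label in the model. It was 67 and 39 without wildtype-labelled VPA replicates 5 and 6, 60 without wildtype-labelled VPA vehicle replicate 3, and 225, 56 and 26 without mutant-labelled VPA replicates 4, 5 and 8. It was 185, 210, 33, 23, 40, 34, 24, 50, 214 and 58 without mutant-labelled VPA vehicle replicates 1, 3, 4, 5, 6, 7, 8, 9, 10 and 11.

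ACY957 was compared with its vehicle in the same way, and Nmu, which encodes the neuropeptide neuromedin U, rose under both labels. In mice labelled wildtype (8 against 5 libraries) Nmu rose by 3.42 (SE 0.56, adjusted p = 0.00142, edgeR), from 0.537 CPM (SD 0.0617, n = 5) to 5.76 CPM (SD 4.74, n = 8), above the highest vehicle library in 8 of 8. Wildtype-labelled ACY957 replicate 8, 1 of the libraries with clock output on the other side, was at 0.786 CPM, within the range of vehicle libraries of other groups, and the next lowest at 1.95 CPM. In mice labelled mutant (8 against 11) it rose by 2.88 (SE 0.38, adjusted p = 4.82e-06, edgeR), from 1.15 CPM (SD 1.63, n = 11) to 8.41 CPM (SD 3.24, n = 8), above the highest vehicle library in 7 of 8. Mutant-labelled ACY957 vehicle replicate 2 was at 6.01 CPM, within the range of treated libraries, and the next highest vehicle library at 1.37 CPM. Without replicate 2, Nmu rose by 3.67 (adjusted p = 2.28e-11, edgeR). Nmu lies on chromosome 5 at 76333495 to 76363788 on the minus strand of mm10, 28702 bases from Clock, which had log2 fold changes of -0.02 (SE 0.11) and 0.02. It was the 1 gene that passed under either label, with 519 and 987 genes at an unadjusted p under 0.05, 1 and 6 by DESeq2 and 0 and 3 by voom. Under the wildtype label Pigs (-0.23), Vip (-1.08), Dtl (-2.41) and Kcnv1 (-0.86) followed without passing. Vip, Dtl and Kcnv1 varied widely in vehicle (Dtl at 1.02 CPM, SD 1.87, and Kcnv1 at 15.4 CPM, SD 14.7, n = 5), and lay under the vehicle median in 6, 4 and 5 of 8 libraries. Under the mutant label Nmur2 (1.79, adjusted p = 0.099, edgeR), Trh (3.14), Gamt (-0.50) and Ccl6 (1.15) followed without passing. Glucocorticoid responsive genes were higher in 13 of 13 under both labels, with medians of 0.40 and 0.56. Under the mutant label 8 rose when adjusted over the list alone (Cdkn1a, Fkbp5, Lcn2, Map3k6, Mt2, Plin4, Sgk1 and Zbtb16), with 0 over all genes (camera adjusted p = 8.59e-09; adjusted p = 0.334 with an estimated correlation). Oligodendrocyte markers were lower in 12 of 12 under the mutant label, with a median of -0.25 and 0 past the threshold over all genes or over the list alone (camera adjusted p = 2.18e-08; adjusted p = 0.334 with an estimated correlation). Nmu under the wildtype label did not pass in voom (2.98, adjusted p = 0.91) or in the fit of the compared groups alone (adjusted p = 0.479), and under the mutant label it did not pass without the 16 vehicle libraries (1.97, adjusted p = 1). That last fit kept vehicle replicates 1 to 4, the high replicate 2 among them. The count under the mutant label was 4 without ACY957 vehicle replicate 2 and 3 without ACY957 replicate 2 or 5.

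Over both labels, a comparison added after the data were examined, 16 ACY957 libraries were set against 16 vehicle libraries. Nmu rose by 2.89 (SE 0.32, adjusted p = 4.55e-09, edgeR) and lay above the vehicle median in 16 of 16 libraries. Nmur2 (chromosome 11, 56024987 to 56041010, minus strand), a receptor of neuromedin U, rose by 1.69 (SE 0.33, adjusted p = 0.0132, edgeR), from 0.229 CPM (SD 0.149, n = 16) to 0.731 CPM (SD 0.282, n = 16), also above the vehicle median in 16 of 16. Maff, a small Maf transcription factor, rose by 0.91 (SE 0.18, adjusted p = 0.0199, edgeR) in 15 of 16, and Atf4, the transcription factor of the integrated stress response, by 0.29 (SE 0.06, adjusted p = 0.0495, edgeR) in 16 of 16. Pigs, a subunit of the enzyme that attaches GPI anchors, fell by 0.21 (SE 0.03, adjusted p = 0.000396, edgeR) in 15 of 16, and Clock had -0.01 (SE 0.07). Cholesterol synthesis genes fell in 5 of 17 (Dhcr7, Fdft1, Fdps, Nsdhl and Sqle) and glucocorticoid responsive genes rose in 8 when adjusted over the list alone, with 0 over all genes in both. Their camera adjusted p of 7.08e-10 and 3.91e-07 became adjusted p = 0.413 with an estimated correlation. These 5 genes passed of 14983, with 1329 at an unadjusted p under 0.05, 28 by DESeq2 and 3 by voom. The count was 19, 3 and 30 without wildtype-labelled ACY957 replicates 3, 6 and 8. It was 10 and 12 without wildtype-labelled ACY957 vehicle replicates 2 and 4. It was 20 and 13 without mutant-labelled ACY957 replicates 1 and 2, and 20 and 12 without mutant-labelled ACY957 vehicle replicates 2 and 11. Nmu passed in every alternative to this comparison. Nmur2, Maff and Atf4 did not pass without the 16 vehicle libraries (adjusted p = 0.501, 0.278 and 0.501). Maff and Atf4 passed neither in voom (adjusted p = 0.143 and 0.0621) nor in the fit of the compared libraries alone (adjusted p = 0.0645 for both). Atf4 was also lost with the genotype label in the model (adjusted p = 0.0691).

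**Figure D4:**
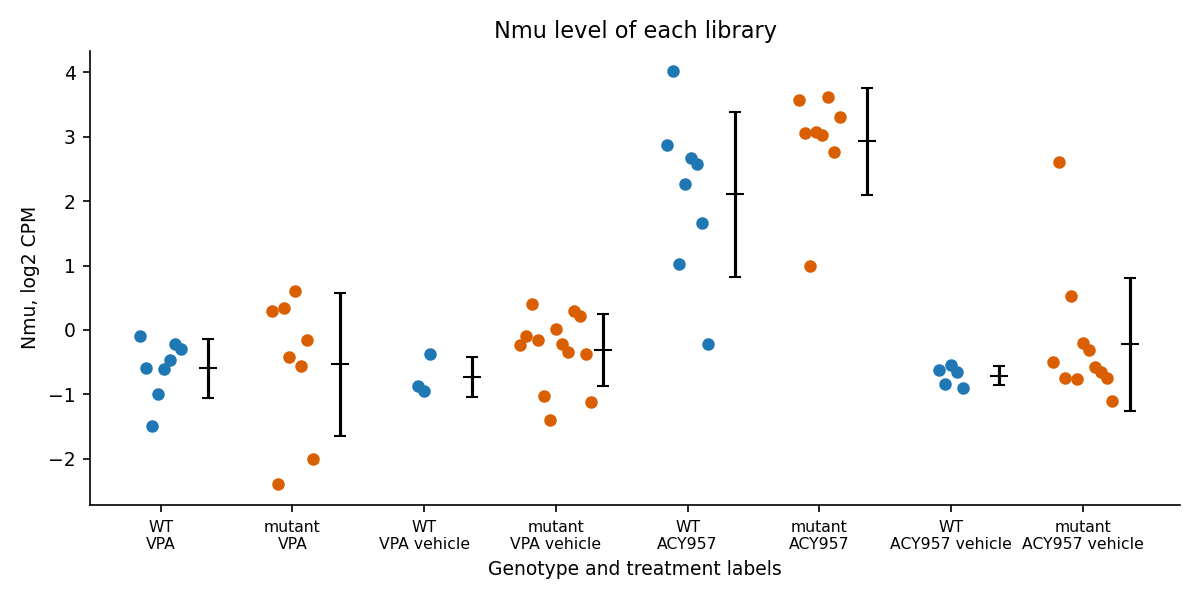
Nmu level (vertical axis, log2 CPM) in each of the 64 libraries by genotype and treatment label (horizontal axis). Points are libraries and bars the group mean and SD; 10 of 16 ACY957 libraries lay above the highest of the 16 ACY957 vehicle libraries.

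The difference of the ACY957 effect between labels gave 0 genes in edgeR, DESeq2 and voom, with 287 at an unadjusted p under 0.05. Clock had 0.04 (SE 0.15), and Dynlt1b (4.25), Trh (4.69), Nov (3.12), Krt2 (3.98) and Krt12 (4.30) had the smallest p, with adjusted p from 0.223 to 0.294 in edgeR. For these 5 genes the SD exceeded the mean in ACY957-treated mice labelled mutant and in ACY957 vehicle mice labelled wildtype, as for Nov (13.6 CPM, SD 22.2, n = 8, and 18.3 CPM, SD 30.7, n = 5). Fold changes of ACY957 under the wildtype and mutant labels had a Pearson r of -0.058 (0.224 by Spearman) across genes (p = 0.792 against 100 permutations, adjusted p = 0.861 over the 7 correlations).

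The VPA and ACY957 effects were set against each other to ask whether the broad and the selective inhibitor act on the same genes. In mice labelled mutant, Pmch was higher in the VPA effect by 4.21 (SE 0.74, adjusted p = 0.00675, edgeR) and Nmu was lower, with -2.90 (SE 0.59, adjusted p = 0.0473, edgeR). Hcrt (4.12, adjusted p = 0.0515), Ergic1 (0.23) and Atf4 (-0.49) followed without passing in edgeR, and Clock had -0.07 (SE 0.13). The Pmch difference was 1.97 without the libraries low in Th (adjusted p = 0.726), 1.48 with Th as a covariate, 1.26 with surrogate variables and 2.28 in voom, with adjusted p from 2.28e-05 to 1 over the alternatives. That of Nmu ranged from -2.24 without the 16 vehicle libraries to -3.69 without mutant-labelled ACY957 vehicle replicate 2. Nmu did not pass in voom, with surrogate variables, with Th as a covariate or in the fit of the compared groups alone. It also did not pass without the libraries low in Th, the libraries discordant in clock output or the 16 vehicle libraries. In the main fit these 2 genes passed, with 1057 at an unadjusted p under 0.05, 4 by DESeq2 and 0 by voom. Without the libraries low in Th, or without the 16 vehicle libraries, the count was 0. It was 0 without VPA replicate 8, and 4 without VPA replicate 1, 3 or 4. It was 1 without VPA replicate 2 or 7, ACY957 replicate 1, 2, 4, 5, 6, 7 or 8, VPA vehicle replicate 2, 3, 4, 7, 8, 9, 10 or 12, or ACY957 vehicle replicate 1, 3, 4, 5, 6, 7, 8, 9, 10 or 11. In mice labelled wildtype 0 genes passed in edgeR, DESeq2 and voom, with 418 at an unadjusted p under 0.05, and Acat3 (-0.90), Rlbp1 (-0.70), Brf2 (0.42), Lect1 (-1.42) and Ccdc94 (-0.57) had the smallest p. The effects of the drugs had a Pearson r across genes of 0.247 under the wildtype label (p = 0.0693, adjusted p = 0.243) and -0.029 under the mutant label (p = 0.861, adjusted p = 0.861), each against 100 permutations. The genotype effect in ACY957 vehicle mice and the VPA effect in mice labelled mutant had r = 0.393 (p = 0.238), and the genotype effect in VPA vehicle mice and the ACY957 effect in mice labelled mutant had r = -0.156 (p = 0.386).

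The vehicles were compared as controls for the drugs. In mice labelled mutant (13 against 11 libraries) Clock had -0.05 (SE 0.08). Protein folding genes were higher with VPA vehicle: of 14 ER stress genes 1 rose over all genes and 8 when adjusted over the list alone (Calr, Dnajb9, Herpud1, Hspa5, Manf, Pdia4, Sdf2l1 and Xbp1), and of 10 heat shock genes 1 and 7. Their camera adjusted p of 0.000893 and 0.000579 became adjusted p = 0.522 with an estimated correlation, and fry gave adjusted p = 0.016 for both. Hspa1b, an inducible chaperone, rose by 1.88 (SE 0.47, adjusted p = 0.0171, edgeR) and lay above the ACY957 vehicle median in 7 of 13 libraries, and Herpud1, of the ER stress response, rose by 0.23 (SE 0.05). Fos, an immediate early gene, rose by 1.34 (SE 0.32) in 12 of 13. Tsc22d3, a glucocorticoid target, rose by 0.45 (SE 0.11) in 13 of 13, and the mitochondrial genes Hadhb and Ndufaf1 by 0.25 (SE 0.05) and 0.27 (SE 0.05) in 13 of 13. Of 16 synaptic vesicle genes 3 fell and 1 rose over all genes, and 4 fell and 2 rose when adjusted over the list alone, without a camera call (adjusted p = 0.171; adjusted p = 0.0116 without the 16 vehicle libraries). Vamp2, a synaptic vesicle protein, fell by 0.23 (SE 0.05), Chrnb2, a nicotinic receptor subunit, by 0.30 (SE 0.06), Scn2b, a sodium channel subunit, by 0.21 (SE 0.05), Ptprn2 by 0.27 (SE 0.05) and Plxna3 by 0.35 (SE 0.07). Rgs9 and Hdac6 fell by 0.37 and 0.18. Slc24a3, Capn5, Astn1, Ergic1, Lhfpl4, Src and Ntn3 fell by 0.30, 0.31, 0.29, 0.16, 0.21, 0.25 and 0.38. Golga7, Fastkd5, Ephx1, Snrnp48, Med7, Hist1h2bc, Fnta, Pglyrp1, Impa1 and Ly6c1 rose by 0.24, 0.34, 0.34, 0.43, 0.27, 0.34, 0.19, 0.47, 0.17 and 0.32. Oligodendrocyte markers rose in 7 of 12 when adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.00131; adjusted p = 0.624 with an estimated correlation). In all, 572 genes passed, 290 higher and 282 lower, with a median size of 0.23, 3285 at an unadjusted p under 0.05, 970 by DESeq2 and 598 by voom. The count was 1 with surrogate variables, 7 without the 16 vehicle libraries (replicates 1 to 4 of each group left) and 305 without the libraries discordant in clock output. It was 331, 316, 381, 903, 308 and 373 without VPA vehicle replicates 1, 4, 5, 6, 11 and 13, and 1033, 292, 366, 337, 241, 307 and 354 without ACY957 vehicle replicates 1, 2, 3, 4, 5, 6 and 8.

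In mice labelled wildtype (3 against 5 libraries) the dopamine receptors and signalling list was higher with VPA vehicle: 11 of 12 were higher, with a median of 0.34, and 6 rose when adjusted over the list alone, among them Adora2a, Drd1 and Drd3, with 0 over all genes. This call held with an estimated correlation (adjusted p = 0.00848) and in fry (adjusted p = 0.0169). It shares its 3 VPA vehicle libraries with the lower level under the mutant label in VPA vehicle mice, so the calls are not independent. Clock had 0.04, and Lrfn4 (-0.49), Rgcc (0.63), Brf2 (-0.37), Bcl7a (-0.32) and Drd1 (1.26) had the smallest p without passing. No gene passed in edgeR, DESeq2 or voom (0 each), with 705 at an unadjusted p under 0.05. Over both labels, a comparison added after the data were examined, 794 of 14983 genes passed, 455 higher and 339 lower, with 3292 at an unadjusted p under 0.05, 1059 by DESeq2 and 735 by voom. Among ER stress genes 6 rose over all genes and 10 when adjusted over the list alone, and among heat shock genes 7 and 8 (camera adjusted p = 2.1e-05 for both; adjusted p = 0.235 with an estimated correlation; fry adjusted p = 0.00165 for both). Hspa1b, Hspb1, Sdf2l1 and Hspd1 rose by 1.86, 0.77, 0.60 and 0.15, Dio2, the enzyme that activates thyroid hormone, by 0.70, and Rgcc and Prosc by 0.42 and 0.20. Lrfn4, Tmem184b, B4galnt4, Bcl7a, Tbc1d22b, Sv2a and Srebf2 fell by 0.30, 0.20, 0.25, 0.19, 0.17, 0.16 and 0.18, and Clock had -0.02 (SE 0.07). With the genotype label in the model the count was 24, with surrogate variables 2009 and without the 16 vehicle libraries 181. It was 448 without wildtype-labelled VPA vehicle replicate 3, 470, 493 and 497 without mutant-labelled VPA vehicle replicates 1, 4 and 11, and 493, 478 and 507 without mutant-labelled ACY957 vehicle replicates 3, 5 and 6.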

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

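All tests of explanations in this part, other than the splits of the libraries, were chosen only after the results were seen. Extreme libraries were looked for with Dixon's test in 40 groups of values, which by chance singles out about 1 in 20 groups. The vehicle groups of 3, 13 and 11 libraries were outside the sizes tested, so their libraries were not screened. Among them, ACY957 vehicle mutant-labelled replicate 11 had Clock at 34.3 CPM, the lowest of the 64 libraries. The next lowest was ACY957 wildtype-labelled replicate 2 at 56.1 CPM.

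The clock output score of VPA-treated mutant-labelled replicate 2 was 5.01, against 4.33 for the nearest of the other 7 libraries, and its Per2 was 3.05 log2 CPM against 1.6. The score of ACY957-treated wildtype-labelled replicate 8 was 4.28, against a nearest value of 5.14, and its Per2 was 1.53 log2 CPM against 2.52. They belong to 13 libraries whose clock output lay on the side of the other genotype label, 8 of them vehicle libraries labelled mutant from mouse 48 on. A different collection time of those 8 libraries stays open, though 53 genes outside the clock lists put 8 of 8 on the wildtype side. These genes were chosen because they differed between genotype labels in drug-treated mice. Whether their levels change with the time of day was not tested, so they cannot decide on collection time. A wrong genotype label of these 8 libraries may be the cause, since the same value of 8 was what it required, and they number 5 in VPA vehicle and 3 in ACY957 vehicle, the excess of each group over 8 mice. Gene by gene, the mean of the 8 lay on the wildtype side in 47 of the 53 and on the mutant side in 6, with Gapdh and Tuba1c on the mutant side in all 8 libraries, which a wrong label does not account for. The 53 genes were chosen between labels that also differ in mouse number. Gapdh and Tuba1c therefore do not decide against a wrong label, since levels that run with mouse number were not separated from genotype. For the other 5 libraries a wrong label stays open: genes chosen in the same way put 3 of the 5 on the side of their clock output, but only ACY957-treated wildtype-labelled replicate 8 clearly (0.25 from the midpoint, the other 4 between -0.02 and 0.07). Those 4, all labelled mutant, had Mthfd1l at 9.5 to 12.4 CPM and Eif5a2 at 104 to 165 CPM. In VPA-treated mice the wildtype-label means were 17.8 and 282 CPM, and the mutant-label means 6.23 and 96.3 CPM (n = 8 each, 1 of the 4 included). These genes therefore placed the 4 between the levels of the labels, and clearly under neither. A biological difference between mice was not tested.

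Th in VPA-treated wildtype-labelled replicate 3 was 6.62 log2 CPM, against 9.13 for the nearest library of its group, and Slc6a3, the dopamine transporter, was 8.07 against 10.71. The VPA effect exceeded the ACY957 effect on Pmch by 4.21 in mice labelled mutant, but by 1.97 without the libraries low in Th (adjusted p = 0.726, and from 2.28e-05 to 1 over the alternatives) and 1.48 with Th as a covariate. An effect of VPA on Pmch and Hcrt in every mouse is argued against, since Pmch lay above the highest vehicle library in 4 of 8 VPA-treated libraries labelled mutant. Hypothalamic tissue in some punches is a candidate explanation that these values leave open: 14 hypothalamic markers other than the genes that passed had a median log2 fold change of 0.47, with 11 higher and 3 lower, and Otp, Isl1, Dlx5 and Trh had 2.44, 1.70, 1.78 and 1.95 without passing. Among VPA-treated libraries labelled mutant, Pmch was highest where Th was lowest. Replicates 8 and 2 had Th at 26 and 44 CPM, Slc6a3 at 6.7 and 66 CPM and Pmch at 542 and 349 CPM. Such values would follow from hypothalamic tissue in these punches. The other libraries low in Th, VPA-treated wildtype-labelled replicate 3 and VPA vehicle mutant-labelled replicate 3, had Pmch at 21 and 12.8 CPM. An effect of VPA in some mice was not tested.

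VPA vehicle and ACY957 vehicle differed in 572 genes in mice labelled mutant, but in 7 without the 16 vehicle libraries and in 1 with surrogate variables. The count of 7 came from replicates 1 to 4 of each vehicle group, so fewer libraries and doubtful labels were not separated. Uneven numbers of libraries with wildtype-level clock output are argued against as the cause, since the fold changes without those libraries were 1.03 times those with them in the median gene. A trend with transcript length and GC content is open: of 607 genes that passed in limma-trend, 48.4% (294) still passed once the trend was removed, among 421 that passed then, while the median size went from 0.22 to 0.18 and the median SE from 0.059 to 0.054. A difference between the whole VPA and ACY957 arms may contribute, since 95.4% of the 572 genes had the same sign between VPA-treated and ACY957-treated mice, a share reached in 1 of 100 permutations. Vehicle composition, batch and handling cannot be separated, since the labels give no date or batch.

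The VPA effect on Lect1 differed between genotype labels by 1.82. The VPA effect on Nmu was below the ACY957 effect in mice labelled mutant, with -2.90 (adjusted p = 0.0473, edgeR). This Nmu difference did not pass in voom, without the low-count filter, with surrogate variables or in the fit of the compared groups alone. Nor did it pass with Th as a covariate, or without the libraries low in Th, the discordant libraries or the 16 vehicle libraries.

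Chance was tested with 40 splits of the libraries of each comparison into groups of the same sizes, the real split included. Only the real split gave as many genes for VPA in mice labelled wildtype (4 genes, 1 in the highest other split). The same was true of the vehicles in mice labelled mutant (572 and 114) and over both labels (794 and 0). This argues against chance without excluding it, since 1 of 40 is the smallest share possible and no correction over comparisons was made. For VPA in mice labelled wildtype the count also fell to 0 without VPA replicate 5. Chance was not argued against for the genotype labels in VPA-treated (157 genes, 1808 in the highest other split), VPA vehicle (1 and 201) and ACY957 vehicle mice (2 and 342), with 2, 10 and 6 splits as large. Nor was it argued against for VPA in mice labelled mutant (9 and 806), ACY957 in mice labelled wildtype (1 and 2) or mutant (1 and 3), or the VPA interaction (1 and 68), with 5, 2, 6 and 10 splits as large. The same held for the difference between drug effects in mice labelled mutant (2; 19), VPA over both labels (107; 127) and ACY957 over both labels (5; 194), with 4, 2 and 2. The splits compare numbers of genes, so where 1 gene passed, any split with 1 gene is as large. They cannot decide on chance for a single gene such as Nmu. Over both labels Nmu lay above the vehicle median in 16 of 16 ACY957 libraries (adjusted p = 4.55e-09, edgeR). Where the real count was 0, every one of the 40 splits is as large by construction and nothing was tested: the genotype labels in ACY957-treated mice (highest other 15), the ACY957 interaction (47), and the difference between drug effects (0) and the vehicles (8) in mice labelled wildtype. Splits with several times the real count, such as 1808, 806, 342, 201 and 194, point to a structure of the samples other than the groups.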

How the results depend on the processing

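The alternatives with Th, with discordant libraries left out and with a genotype term, and most single libraries left out, were chosen only after the data were examined, and where a result changed the cause was not tested. Counts are given in the order named. With DESeq2 the genotype labels gave 262 genes in VPA-treated, 5 in ACY957-treated and 2 in VPA vehicle mice, VPA and ACY957 in mice labelled mutant 28 and 6, their difference 4, the vehicles in mice labelled mutant 970, and VPA and ACY957 over both labels 179 and 28. With voom the genotype labels in ACY957 vehicle mice gave 1, VPA and ACY957 in mice labelled mutant 0 and 3, ACY957 in mice labelled wildtype 0, the difference between drug effects in mice labelled mutant 0 and ACY957 over both labels 3. Without the low-count filter the genotype labels in VPA vehicle mice gave 3, VPA in mice labelled mutant 20, the VPA interaction 2 and the difference between drug effects 1. Fits of the compared groups alone gave 73, 8, 0 and 0 for the genotype labels in VPA-treated, ACY957-treated, VPA vehicle and ACY957 vehicle mice, and 0 for VPA in mice labelled mutant. They gave 0 and 2 for ACY957 in mice labelled wildtype and mutant, 0 for the VPA interaction, 0 for the difference between drug effects, 318 for the vehicles in mice labelled mutant, and 0 and 2 for VPA and ACY957 over both labels. With surrogate variables the genotype labels gave 104 in VPA-treated and 0 in VPA vehicle mice, and VPA 7 and 3 and ACY957 2 and 3 in mice labelled wildtype and mutant. The VPA interaction then gave 0, the difference between drug effects 0, the vehicles 1 and 1 in mice labelled wildtype and mutant, and ACY957 and the vehicles over both labels 188 and 2009. Without the 16 vehicle libraries the genotype labels gave 253, 20, 4 and 22 (in the order above), VPA and ACY957 in mice labelled mutant 0 and 0, the VPA interaction 0, the difference between drug effects 0, the vehicles in mice labelled mutant 7, and VPA, ACY957 and the vehicles over both labels 1, 2 and 181. With both vehicles pooled the genotype labels in vehicle mice, set against the VPA vehicle count, gave 3, and VPA and ACY957 in mice labelled mutant 130 and 119. Without the libraries low in Th the genotype labels in VPA-treated mice gave 84, VPA and ACY957 in mice labelled mutant 2 and 2, the difference between drug effects 0, the vehicles in mice labelled mutant 952 and ACY957 over both labels 9. With Th as a covariate these were 71, 2, 2, 0, 1286 and 13, with 2 for the genotype labels in VPA vehicle mice, and 68 and 1269 for VPA and the vehicles over both labels. Without the discordant libraries VPA and ACY957 in mice labelled mutant gave 2 and 8, the VPA interaction 0, the difference between drug effects 0, the vehicles in mice labelled mutant 305, and VPA and ACY957 over both labels 7 and 35. With the genotype label in the model VPA and the vehicles over both labels gave 11 and 24. Of 99 gene list calls by camera over the 14 planned comparisons, 2 were also made with an estimated correlation, 5 by fry and 68 in the same direction without the 16 libraries. The correlation of the VPA effects between genotype labels was 0.169 without the 16 libraries, and that of the ACY957 effects was 0.224 by Spearman, against -0.058 by Pearson, and 0.33 over genes of at least 10 CPM. By Spearman and over those genes the drug effects in mice labelled mutant had 0.11 and 0.203, against -0.029, and the genotype effects in drug-treated mice 0.009 and 0.004, against -0.104, none past the threshold. Of 6685 values of named genes under an alternative, 6066 kept their direction and side of the threshold or passed in neither, 62 passed newly and 557 no longer passed. Among the 6066, 39 changed sign in a gene that passed in neither setting, 36 of them values of Clock.

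Leaving out single libraries gave ranges of 51 to 504, 0 to 2, 0 to 2 and 0 to 3 for the genotype labels in VPA-treated, ACY957-treated, VPA vehicle and ACY957 vehicle mice. The ranges were 0 to 5 and 3 to 269 for VPA and 1 to 1 and 1 to 4 for ACY957 in mice labelled wildtype and mutant, 0 to 2 and 0 to 0 for the VPA and ACY957 interactions, and 0 to 4 and 0 to 0 for the difference between drug effects in mice labelled mutant and wildtype. They were 0 to 0 and 241 to 1033 for the vehicles in mice labelled wildtype and mutant, and 23 to 225, 3 to 30 and 448 to 1151 for VPA, ACY957 and the vehicles over both labels. Total counts of 20.1 M to 37.5 M limit what low-count genes such as Nmur2 can show.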

Other observations

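The test of passenger variants in this part was chosen only after the genotype result was seen, and the gene lists were fixed before the data were examined. The lists of histone deacetylase genes and of genes responsive to deacetylase inhibitors, 8 of whose 11 members are in other lists too, gave no camera call between either drug and its vehicle. For the histone deacetylase list the camera adjusted p was 0.944 under VPA and 0.932 under ACY957 in mice labelled wildtype, and 0.786 and 0.501 in mice labelled mutant. For the inhibitor responsive list it was 0.744 and 0.918 under VPA and 0.527 and 0.73 under ACY957, in mice labelled wildtype and mutant. Over both labels it was 0.793 under VPA and 0.533 under ACY957 for the first list, and 0.991 and 0.535 for the second.

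Passenger variants beside Clock on chromosome 5, from the strain that carried the mutation, are a possible explanation of genes that differ between genotype labels. Of 149 genes that passed in VPA-treated mice and have a position, 0 lay within 10 Mb of Clock, against 64 of 14888 other genes (0.43%, Fisher's exact test, two-sided p = 1). Variants that change only genes inside that window therefore account for none of these 149. Variants farther from Clock, or acting on genes elsewhere, were not tested. So few genes lie in the window that the test could not tell a lower share from an equal one.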
